A study of Mus musculus with 34 samples.

How the data were processed

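RNA was measured by sequencing in 30 libraries of mouse F1(G4) embryonic stem cells (ESCs; strain 129S2/C57Bl6J), wild type or mutant for the long non-coding RNA Handsdown (Hdn), as undifferentiated ESCs and on days 3, 4, 5 and 6 of differentiation with BMP4. Per the labels' protocols, the cells were grown in 2i medium, aggregated in hanging drops and plated on fibronectin in serum-free medium with 20 ng/mL BMP4, and total RNA was made into ScriptSeq v2 libraries. The labels conflict in 2 places: the design text of the series names Brachyury mutants where all sample labels name Hdn, and the growth protocol of the RNA samples describes dissected embryonic hearts where titles and treatment protocol describe ESC differentiation. The sample labels, titles and treatment protocol were followed. Each of the 10 groups held 3 libraries. The titles call the mutant cells Hdn null, and the labels do not state what sequence change was made, how many mutant clones were used or whether the replicates are separate cultures. The series lists 34 samples. Its 3 chromosome conformation (4C) samples and its 1 library of embryonic hearts were not analysed here.

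The deposited table gives RPKM, read counts normalised by the authors to gene length and library size, for 52636 Ensembl mouse genes in the 30 libraries, of which 52403 carried a symbol in the gene table used and 233 did not. Per the submitters' processing notes, the RNA reads were processed with STAR and DESeq2 against mm10, and the versions, gene annotation, read counting and strand setting are not given in the sources used here. No batch, date or lane is given in the labels. Gene positions and spans came from a RefSeq table of GRCm38.p6, the assembly also called mm10. Read totals were inferred from the step between the smallest RPKM values of genes of equal length, and gave 43.3 to 68.4 M reads per library, with a median of 57.2 M. Counts for single genes were derived from these totals, cover counting error only, and were used for the Hdn locus and the Y-linked Kdm5d alone. A count of 0 allows up to 3 reads in a library.

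The deposited RPKM were divided by a size factor per library, the median ratio to the gene-wise geometric mean over 11618 genes above 0 in all libraries and at 1 or more on average. The size factors lay between 0.888 and 1.106. The results are called scaled RPKM below. Genes at 1 or more scaled RPKM in at least 3 libraries were kept, which left 14196 genes. The log2 of scaled RPKM plus 0.5 was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 30 libraries and a mean-variance trend. Mutant was compared with wild type at each of the 5 stages and on average over stages, an F test asked whether the mutant difference depended on stage, and each wild-type stage was compared with the stage before it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 in size, and "rose", "fell", "higher" and "lower" are used in that sense. Adjusted p for genes are from limma over the 14196 genes unless another test is named. Hdn lay below the filter and was compared by an exact permutation test at each stage and by a permutation test within stages with 100000 resamples, each two-sided.

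The choices of scaling, filter, thresholds, tests, gene lists and named genes were made before the data were examined. The 18 gene lists covered the Hand2 locus, pluripotency, primed epiblast, primitive streak, cardiac progenitors, contractile genes, mesenchyme and smooth muscle, endothelium and blood, endoderm, neural genes, trophoblast and surface ectoderm, BMP targets, Wnt targets, the cell cycle, p53 targets, imprinted genes, Y-linked genes with Xist, and mitochondrially encoded genes. The 17 lists with at least 4 measured genes were tested against all other genes with camera in limma, with a preset correlation of 0.01, adjusted over all lists and stages. The camera test was repeated with an estimated correlation and the lists were tested with fry. A gene's count "adjusted over the list alone" uses the Benjamini-Hochberg adjustment within its list. The named genes are the 8 largest rises and falls per mutant comparison among called genes whose 3 mutant values lay outside the wild-type range (for the average, genes with 1 sign at all 5 stages), the 4 largest per direction for each wild-type comparison, up to 4 members per list ranked by adjusted p, and all neighbours of Hand2. Unnamed, Gm, Rik and pseudogene symbols were passed over for naming, and any gene named outside this rule is said to be so. Chance puts 3 values outside the range of 3 others, in either direction, for 10% of genes.

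The alternatives were no scaling, scaling to the same sum, quantile normalization, pseudocounts of 0.1 and 1, no filter, a filter of 5, adjusted p alone, limma without the trend, only the 6 libraries compared, the replicate number as a block, camera with an estimated correlation, fry, and leaving out each replicate. After the data were seen, 3 were added: leaving out the 5 mutant libraries that hold mature heart and adult globin transcripts, subtracting that shared signal, and, for day 6, subtracting a larger signal. The subtraction takes from these 5 libraries, for each gene, its smallest slope on the adult beta globin level within mutant days 4, 5 and 6, times the library's globin level. Where the smallest slope is negative, 0 is used in its place and nothing is taken. The larger signal uses in place of that slope the larger of the gene's excess in mutant day 4 replicate 3 and day 5 replicate 3 over the fellow replicates, per unit of globin, so that ordinary differences between replicates are scaled up with it. Marker lists for heart tissue, adult globin, embryonic globin, early cardiac genes, placenta and methylation-silenced germline genes were added at the same time, those for heart tissue, placenta and germline genes before the values of their genes were examined. Enrichment of X-linked genes among called genes was tested with Fisher's exact test, with the kept X-linked and autosomal genes as background.

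The fit was tested on simulated data made for mutant against wild type at day 6 with 13753 genes, of which 200 were changed, 40 at each fold. It called 0% of genes changed 1.5-fold, 27.5% of those changed 2-fold, 85% at 3-fold, 95% at 4-fold and 100% at 8-fold, with 4 unchanged genes called. Adjusted p alone called 40%, 55%, 90%, 95% and 100% of them. In a simulation with 14196 genes, a list of 16 genes raised 2-fold had a camera adjusted p of 6.3e-14 and 0 other list tests were called. The simulated genes varied independently, so list calls that come from correlation between genes were not tested. A shared signal was also simulated in the 5 mutant libraries that hold heart transcripts, for 60 genes at a mean under 5 scaled RPKM. At day 6, 60 of them were called before the subtraction and 8 after it. Genes at higher levels were not simulated, so the subtraction was not tested for them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, other tests and figures.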

Results

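Gene expression was measured by total RNA sequencing in mouse ESCs and on days 3, 4, 5 and 6 of BMP4-driven differentiation, in wild-type cells and in cells mutant for Hdn, a long non-coding RNA transcribed next to Hand2. Hand2 encodes a transcription factor needed for heart and limb development. The 30 libraries form 10 groups of 3, and n = 3 for each mean ± SD below. Read totals inferred from the RPKM values ranged from 43.3 to 68.4 M reads per library, and 10607 to 12004 genes per library were at 1 RPKM or more. The 10 most abundant genes made up 7.6 to 13.6% of the RPKM of a library. A total of 17475 genes were at 0 in all libraries. Libraries of the same group correlated across genes with r from 0.9525 to 0.9968. The lowest values belonged to mutant day 4 replicate 3, with r = 0.9525 and 0.9625 to its fellow replicates.

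The targeted gene was examined first. Hdn, listed as 5033428I22Rik (ENSMUSG00000097910), lies on chromosome 8 at 57332435 to 57354580 in GRCm38, 7918 bp from Hand2 (57320983 to 57324517). Wild-type ESCs had 0 Hdn reads in all 3 libraries. On day 5 the wild-type libraries had 19, 24 and 29 reads, and on day 6 they had 60, 37 and 240. Mutant libraries had 0 reads through day 4, then 0, 0 and 1 on day 5 and 0, 8 and 3 on day 6. The mean level on day 6 was 0.162 ± 0.157 scaled RPKM (SD, n = 3) in wild type and 0.00565 ± 0.00607 in mutants. The exact permutation test gave p = 0.1 on days 4, 5 and 6, which is the smallest p that 3 against 3 libraries allow, and p = 0.4 on day 3. Over all 30 libraries, permuted within stages, the mutant mean was lower by a difference of -0.0403 scaled RPKM (permutation p = 5e-05). The number of resamples sets a floor of 1e-05, and ties at 0 put the smallest p that these data allow above it. The 3 mutant libraries with Hdn reads are among 5 that hold mature heart transcripts, described below with day 4.

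**Figure D1:**
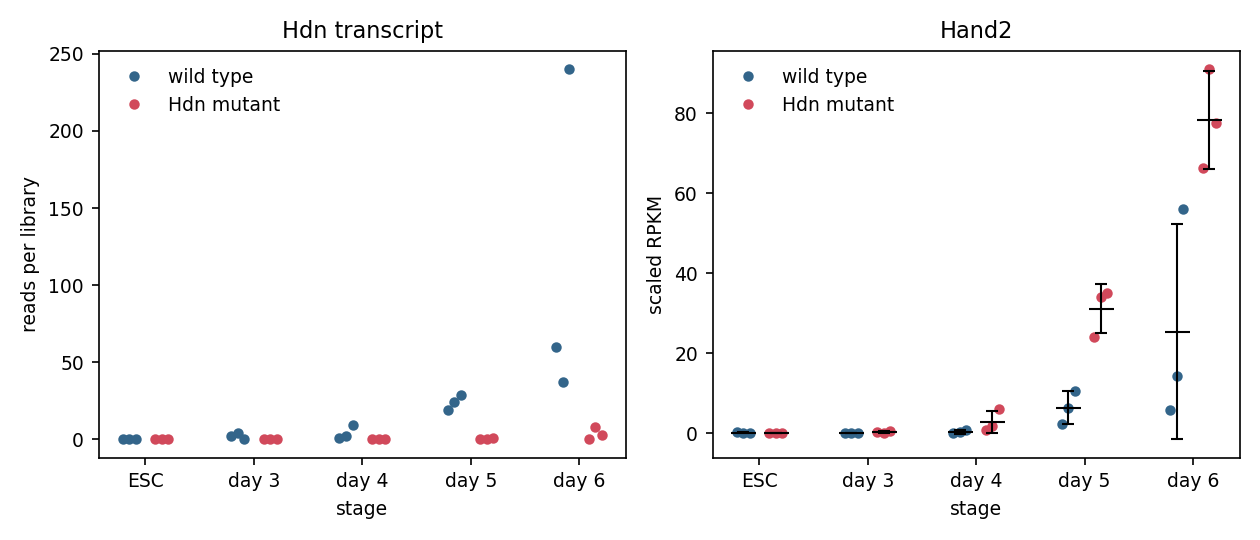
Hdn in reads per library (left) and Hand2 in scaled RPKM (right) by stage, with 1 point per library, in wild type and Hdn mutants. On day 6 Hand2 lay between 66.3 and 91 in the mutant libraries and at 5.76, 14.4 and 56 in wild type.

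Hand2 was higher in mutants from day 4. Its level on day 5 was 31.1 ± 6.11 scaled RPKM in mutants and 6.4 ± 4.14 in wild type, a log2 change of 2.39 (SE 0.58, limma adjusted p = 0.004). On day 6 it was 78.3 ± 12.3 against 25.4 ± 26.9, a log2 change of 2.17 (adjusted p = 0.0067). The day 4 change was 1.73 (adjusted p = 0.034), and the values on day 3 (0.66, adjusted p = 0.51) and in ESCs (-0.11, adjusted p = 0.91) did not pass. Hpgd, which encodes a prostaglandin-degrading enzyme and lies 999937 bp from Hand2, fell on days 4, 5 and 6 by log2 changes of -1.76, -2.31 and -2.11 (SE 0.25, largest adjusted p = 1.7e-05). Sap30, Hmgb2, Galnt7, Fbxo8 and Cep44 did not pass at any stage. The list of the locus, which holds Hand2 itself beside its neighbours, with 7 of 10 genes measured, was not called at any stage (camera adjusted p from 0.39 to 0.8). Hand2os1, whose span ends 124 bp from Hand2, was below the filter, with 450, 908 and 722 reads in mutants and 40, 121 and 595 in wild type on day 6. Gm34030, which overlaps Hdn, had 2, 7 and 8 reads in mutants and 26, 24 and 128 in wild type on day 6. The spans of Gm34030 and Hdn overlap and the counting of reads in overlaps is not given, so the read numbers of both are uncertain to that extent. The day 6 Hand2 call was lost without wild-type day 6 replicate 1 (log2 change 1.43, adjusted p = 0.064) and with only the 6 libraries compared (adjusted p = 0.087). The day 4 call was lost without mutant day 4 replicate 3 (1.1), without wild-type day 4 replicate 1 (1.41) and without wild-type day 4 replicate 2 (1.67), and also with only the 6 libraries compared (adjusted p = 0.16), a pseudocount of 1 (adjusted p = 0.077), no filter (adjusted p = 0.081) and the heart signal described with day 4 subtracted (1.41, adjusted p = 0.058). Without the 5 libraries that hold that signal the day 5 change was 2.3 (adjusted p = 0.011), and after its subtraction the day 6 change was 1.65 (adjusted p = 0.022). The dependence of the Hand2 difference on stage had an adjusted p of 0.06.

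The wild-type course compares the wild-type libraries stage by stage. The Y-linked Eif2s3y was at 0.354, 0.227 and 0.437 RPKM as deposited in wild-type ESCs and at 3.81, 4.00 and 3.29 on day 3. The steps from ESCs may therefore hold differences between cultures besides differentiation, which was not tested. Between ESCs and day 3, Hand1, a transcription factor of early mesoderm and trophoblast, rose from 0.262 ± 0.247 to 161 ± 36.1 scaled RPKM (log2 change 7.76, SE 0.28, adjusted p = 3.7e-17). Fgf8, a signal of the primitive streak, rose by 7.41 on the log2 scale and the imprinted RNA H19 by 7.55, while Notum, a Wnt inhibitor, changed by -5.73. From day 3 to day 4, Mesp1, a regulator of cardiac mesoderm, rose from 0.569 ± 0.499 to 23.8 ± 23 (log2 change 3.66, SE 0.88, adjusted p = 0.011), and the retinoic acid-degrading enzyme Cyp26a1 rose by 3.51, while the transcription factor Etv4 fell (-1.88). From day 4 to day 5, Hand2 rose by 2.87 (SE 0.58, adjusted p = 0.0049) and the T-box factor Tbx2 by 2.13, and Foxj1, a regulator of motile cilia, fell (-2.11). From day 5 to day 6 the gut peptide gene Pyy rose by 2.31 (SE 0.48, adjusted p = 0.018), and the Notch ligand Dll3 (-2.55) and the Nodal antagonist Cer1 (-2.21) fell. By day 6, H19 and the growth factor gene Igf2 were above ESCs by 9.46 and 9.28, and the Nodal inhibitor Lefty2 was below them (-5.99).

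In wild type, 2471 genes rose and 2883 fell from ESCs to day 3, 267 rose and 66 fell to day 4, 156 rose and 59 fell to day 5, and 24 rose and 7 fell to day 6. Between ESCs and day 6, 2946 rose and 3041 fell. With each library scaled to the same sum, the first step gave 1905 rises and 3586 falls and moved the median of all genes by -0.2 (log2), and without scaling the median shift from ESCs to day 6 was 0.19. The day 4 step gave 324 rises and 39 falls with that sum, and the last step 36 and 5 with that sum and 19 and 11 with quantile normalization. The later steps moved with single libraries. The day 4 step gave 359 rises and 116 falls without wild-type day 4 replicate 1 and 174 and 35 without replicate 2. The day 5 step gave 92 and 48 without day 4 replicate 1, and 232 and 132, 90 and 24, and 105 and 23 without day 5 replicates 1, 2 and 3. The day 6 step gave 39 and 5, 59 and 12, and 14 and 1 without day 5 replicates 1, 2 and 3, 89 and 13, 20 and 4, and 19 and 3 without day 6 replicates 1, 2 and 3, and 39 and 14 with the replicate number as a block. With only the 6 libraries compared, limma called 0 genes in the steps to day 5 and day 6, with 1721 and 662 genes at an unadjusted p under 0.05, so every gene named for those steps lost its call there. The Mesp1 call was lost without wild-type day 3 replicate 1 (3.19) and day 4 replicates 2 (3.19) and 3 (2.69), and with only the 6 libraries compared (adjusted p = 0.13). The Pyy call was lost without day 5 replicate 1 (2.1) or 3 (2.22) or day 6 replicate 2 (1.84) or 3 (2.06) and with a pseudocount of 0.1 (adjusted p = 0.069), and the Cer1 call without day 5 replicate 3 (-1.9) or day 6 replicate 3 (-1.82). The Foxj1 call was lost without day 4 replicate 3 (-1.79) or day 5 replicate 2 (-1.98). The Dll3 call was lost without any 1 of day 5 replicates 1 and 3 and the 3 day 6 libraries (-2.71 to -2.29), and with the same sum, a pseudocount of 0.1, no filter and a filter of 5.

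The mutant and wild-type ESCs were compared before differentiation. Mitochondrially encoded transcripts were higher in mutant ESCs, with 8 of 9 genes up (median log2 change 1.35, camera adjusted p = 0.00043; adjusted p = 0.47 with an estimated correlation). Among them, mt-Cytb was at 1690 ± 682 scaled RPKM in mutants and 411 ± 83.7 in wild type (log2 change 1.96, SE 0.31, adjusted p = 1.9e-05), and mt-Atp6 rose by 2.23. The chaperone gene Hsp90aa1 rose from 86.3 ± 20.6 to 609 ± 247 (log2 change 2.74, SE 0.24, adjusted p = 5.2e-09). The cell cycle genes Top2a, Bub1 and Mki67 rose by 1.76, 1.87 and 1.89, and the p53 targets Ccng1, Trp53inp1, Pmaip1 and Mdm2 by 1.43, 1.58, 1.48 and 1.04. The caudal-type factor Cdx1 fell from 98.6 ± 19.4 to 19.3 ± 17.8 (log2 change -2.67, SE 0.35, adjusted p = 1.6e-06), and the collagen gene Col9a2 (-3.43) and the water channel gene Aqp3 (-2.22) fell as well.

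In total 1214 genes were higher and 444 lower in mutant ESCs. The mitochondrial list was the 1 list called, with 8 genes higher when adjusted over the list alone. The mitochondrial share of RPKM was 3.02, 6.39 and 6.22% in the mutant ESC libraries and 1.67, 1.46 and 2.15% in wild type. The p53 list had 4 of 12 genes higher and 1 lower, a median of -0.11 and a mean of 0.23 (camera adjusted p = 0.4, upward), and the cell cycle list had 3 of 16 higher and 1 lower, a median of -0.12 and a mean of 0.15 (adjusted p = 0.82, upward). Imprinted genes had 5 of 16 higher, among them Peg3 (1.41) and Impact (1.72), with adjusted p = 0.29 for the list. Of them 3 were higher without wild-type ESC replicate 1 or with quantile normalization, and 2 without mutant ESC replicate 2 or 3 or with a pseudocount of 1. The p53 list had 2 lower without mutant ESC replicate 1 and 0 without replicate 2 or 3, and the cell cycle list had 0 lower without wild-type ESC replicate 1 or 2 or mutant ESC replicate 2 or 3. Both had 0 lower without scaling, with the same sum and with quantile normalization. The pluripotency list was not called, with 1 of 20 genes higher, which was Zfp42 (1.11), also known as Rex1. Of the primed epiblast factors, Otx2 (1.64) rose and Zic2 (-1.79) fell. Of the BMP targets, Smad6 (-1.16) and Id1 (-1.31) fell. Zfp980, Zfp987, Zfp990, Zfp534 and Rex2, zinc finger genes, rose by 2.72 to 3.06 and are uncertain, since near-identical copies can share reads and the handling of such reads is not given. The Y-linked Eif2s3y and Ddx3y rose by 3.72 and 2.83, Ddx3y sharing sequence with an X-linked copy. Eif2s3y stood at 0.368 ± 0.101 scaled RPKM in wild-type ESCs, between 3.71 and 4.39 on average on wild-type days 3 to 6, and at 12.1 ± 5.84 in mutant ESCs. The Y-linked Kdm5d, below the filter, had 45 to 174 reads in the mutant libraries and 3 to 32 in wild type over all 5 stages. The split between rises and falls depended on the scaling: 1472 and 257 without scaling, and 1601 and 268 with each library at the same sum. Without mutant ESC replicate 1, 1589 genes were higher and 963 lower, and the Mdm2 call was lost without mutant ESC replicate 2 (0.96) or 3 (0.94) and with a pseudocount of 1 (0.99).

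**Figure D2:**
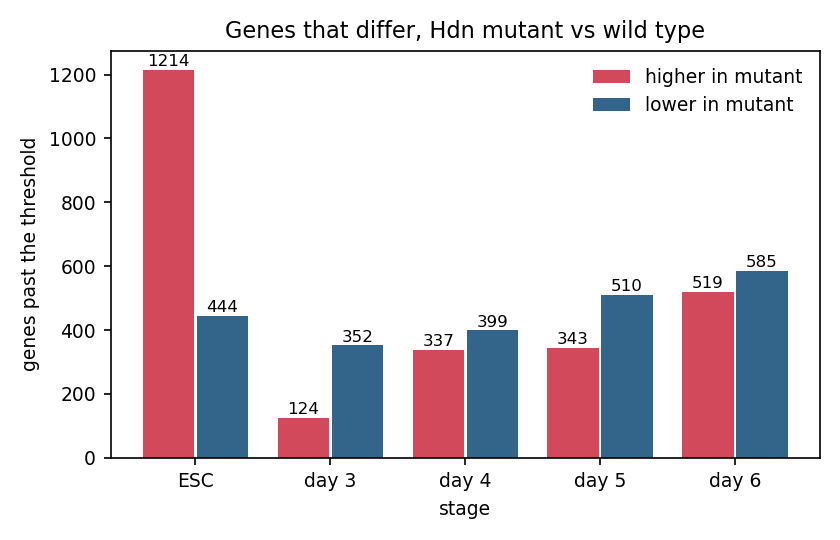
Number of genes past the threshold (adjusted p under 0.05 and log2 change of at least 1), higher or lower in Hdn mutants, at each stage. ESCs had 1214 higher and 444 lower, day 3 had 124 and 352, and day 6 had 519 and 585.

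On day 3 the comparison asked how mutant cells differ early in differentiation. Of 20 pluripotency genes 11 were lower in mutants, and of 12 measured trophoblast and surface ectoderm genes 7 were lower. Both lists had a camera adjusted p of 6.9e-08, and with an estimated correlation an adjusted p of 0.13 and 0.077. Zfp42 fell from 15.1 ± 2.3 to 3.07 ± 0.455 scaled RPKM (log2 change -2.13, SE 0.16, adjusted p = 5.7e-09), and Klf2, a naive pluripotency factor, from 93.8 ± 17.6 to 6.96 ± 0.869 (log2 change -3.65, SE 0.63, adjusted p = 0.00022). H19 showed the largest fall among the named genes, from 342 ± 85 to 7.08 ± 1.32 (log2 change -5.48, SE 0.35, adjusted p = 8e-10). The trophoblast factors Ascl2 (-2.9) and Tfap2c (-1.8), the keratins Krt7 (-2.04) and Krt8 (-1.56), and Hand1 (-1.33) fell too. Apln, which encodes the peptide ligand of the apelin receptor, rose from 3.55 ± 2.65 to 19.3 ± 4.58 (log2 change 2.61, SE 0.49, adjusted p = 0.00058), and Bmp4 rose by 1.6.

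The pluripotency genes had a median of -1.41, and 12 fell when adjusted over the list alone. The trophoblast genes had a median of -1.19, and 7 fell when adjusted over the list alone. The primitive streak list was called upward (median 0.62, camera adjusted p = 0.022; adjusted p = 0.74 with an estimated correlation) although 1 of its 17 genes rose and 1 fell, and the same counts held when adjusted over the list alone. The list was not called without wild-type day 3 replicate 1 (camera adjusted p = 0.24), without mutant day 3 replicate 3 (0.41) or with the same sum (0.083), and 2 of its genes rose without wild-type day 3 replicate 3. The 2 genes of the count were the activin antagonist Fst (1.75) and Cdx1 (-1.25). The cell cycle list was called upward with a median of 0.25 and 0 of 16 genes past the threshold (camera adjusted p = 0.00019; adjusted p = 0.077 with an estimated correlation), also when adjusted over the list alone. Imprinted genes split, with Peg10 (-2.8) and Cdkn1c (-1.51) among 4 that fell and Grb10 (1.02; lost without wild-type day 3 replicate 1 or 3 or mutant day 3 replicate 1 or 2, and with a pseudocount of 1) among 2 that rose. Of them 1 rose without wild-type day 3 replicate 1 or 2 or mutant day 3 replicate 2 or with a pseudocount of 1, and 0 without wild-type day 3 replicate 3 or mutant day 3 replicate 1. The median of the list was 0.07 and its mean -0.47 (camera adjusted p = 0.57, downward). The blood and endothelial factor Gata2 (-2.77) and the Wnt antagonist Dkk1 (-1.95) fell. The endoderm list had a median of -0.17 and a mean of 0.01 (camera adjusted p = 0.83, downward), and the BMP and contractile lists were not called. Rhox6 (-5.09), Rhox9 (-4.74) and Rhox5 (-3.13), X-linked homeobox genes of placenta and germline, fell, and are uncertain since copies in their cluster can share reads. A total of 124 genes were higher and 352 lower (167 and 268 with each library at the same sum). The Fst call was lost without wild-type day 3 replicate 1 (1.02), mutant day 3 replicate 2 (1.81) or 3 (1.39), with a pseudocount of 0.1 (adjusted p = 0.055), no filter (adjusted p = 0.093) and only the 6 libraries compared (adjusted p = 0.11). The Cdx1 call was lost without wild-type day 3 replicate 1 (-1.05) or mutant day 3 replicates 1 (-1.18) or 2 (-1.2) and with a pseudocount of 1 (-0.98), and the Hand1 call with a pseudocount of 0.1 (adjusted p = 0.056).

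From day 4, 5 mutant libraries held transcripts of mature heart muscle and of adult red cells. The ventricular myosin gene Myl2 was at 17.1 scaled RPKM in mutant day 4 replicate 3, 20.7 in day 5 replicate 3, and 45.2, 129 and 115 on day 6. The adult beta globin gene Hbb-bs was at 19.8, 27, 61, 181 and 155 in the same libraries. In the other mutant libraries of days 4 and 5, Myl2 lay between 0.117 and 0.154 and Hbb-bs between 0 and 0.16. Cox8b, a cytochrome oxidase subunit of adult muscle, was named after its values were seen. It was at 0 in all 15 wild-type libraries and between 3.02 and 18.8 in these 5. The counts and the called lists of days 4 and 5 are therefore given also without these libraries and those of day 6, where all 3 mutant libraries hold the signal, after its subtraction.

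**Figure D3:**
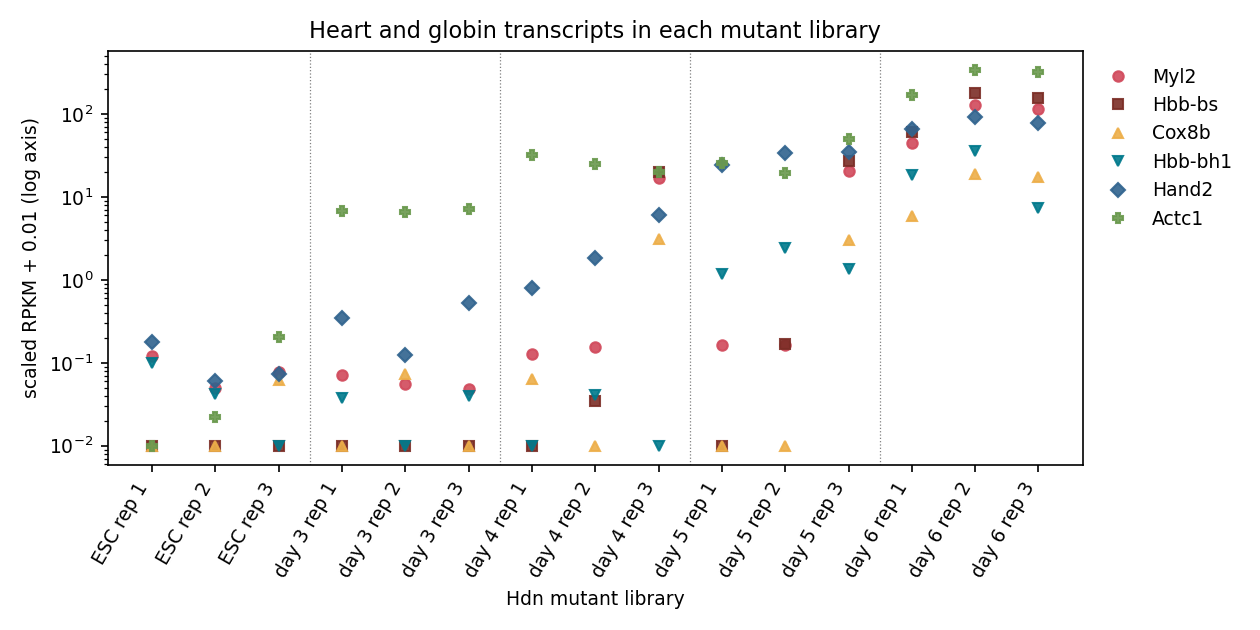
Levels of heart muscle and globin genes in the 15 Hdn mutant libraries, in scaled RPKM plus 0.01 on a log axis. Myl2 and Hbb-bs stand above the other libraries in day 4 replicate 3, day 5 replicate 3 and all 3 day 6 libraries.

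On day 4, 8 of 13 BMP targets and 5 of 16 cardiac progenitor genes (8 without mutant day 4 replicate 1) were higher in mutants, and 12 of 20 pluripotency and 5 of 12 trophoblast genes were lower. With an estimated correlation these lists had an adjusted p of 0.077, 0.28, 0.13 and 0.2 in that order. Bmp4 rose from 7.44 ± 2.18 to 95.5 ± 43.1 scaled RPKM (log2 change 3.54, SE 0.39, adjusted p = 6.4e-07), and its inhibitor Smad6 from 10.6 ± 0.835 to 24.3 ± 4.31 (log2 change 1.15, SE 0.2, adjusted p = 0.0002). Foxf1, a factor of lateral mesoderm, rose by 2.9, and the cardiac progenitor genes Isl1, Pdgfra, Gata6 and Tbx20 by 1.81, 1.35, 1.63 and 1.66. Cdx2, a caudal-type factor of posterior mesoderm and trophectoderm, rose by 2.26. Tfap2c fell from 33.4 ± 15.3 to 5.18 ± 0.984 (log2 change -2.49, SE 0.29, adjusted p = 1.3e-06), and Ascl2 (-3.57) and H19 (-4.63) fell with it.

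Of 13 measured BMP targets, 8 rose, and 8 when adjusted over the list alone and 4 with only the 6 libraries compared (median 1.15, camera adjusted p = 5.1e-08; adjusted p = 0.077 with an estimated correlation). Cardiac progenitor genes rose in 5 of 16, and in 5 when adjusted over the list alone (median 0.76, camera adjusted p = 0.00018; adjusted p = 0.28 with an estimated correlation). Of them 8 rose without mutant day 4 replicate 1, 9 with a pseudocount of 0.1, 3 with a pseudocount of 1 or a filter of 5, and 2 with only the 6 libraries compared. The streak list rose in 4 of 17, and in 6 when adjusted over the list alone (median 0.88, camera adjusted p = 0.014; adjusted p = 0.74 with an estimated correlation). Without wild-type day 4 replicate 1 it rose in 1 and was not called (camera adjusted p = 0.46), as Wnt3 (1.07 to 0.65), Lhx1 (1.33 to 0.64) and Mesp2 (1.33 to 0.45) lost their calls. Mesp2 lost its call also without mutant day 4 replicate 1 (1.3) or 2 (1.1), without scaling, and with the same sum, a pseudocount of 0.1, no filter and the replicate number as a block. It rose in 8 without wild-type day 4 replicate 3, in 7 without mutant day 4 replicate 3, in 2 with the same sum and in 1 with only the 6 libraries compared. The list was also not called without mutant day 4 replicate 1 (0.052) or 2 (0.077) or with only the 6 libraries compared (0.071). Of 23 contractile genes, 3 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone (median 0.7, camera adjusted p = 0.00043; adjusted p = 0.47 with an estimated correlation). They include cardiac troponin C, Tnnc1 (2.1), and atrial myosin Myl4 (-1.65). Without wild-type day 4 replicate 2, 1 rose, as the cardiac actin Actc1 (1.37) and the troponin I gene Tnni1 (1.69) lost their calls. Actc1 lost its call also without wild-type day 4 replicate 3 (1.65) or mutant day 4 replicate 1 (1.52) or 2 (1.69), and Tnni1 without wild-type day 4 replicate 1 (1.62) or mutant day 4 replicate 2 (1.94) or 3 (1.27) and after subtraction of the heart signal (1.28, adjusted p = 0.12). With no filter both lost their calls, and Tnni1 also with a pseudocount of 1 and with only the 6 libraries compared. The rises were 8 with a pseudocount of 0.1, 1 with no filter and 5 with the replicate number as a block. Of 11 mesenchyme genes 2 rose, Vim (1.68) and Col1a1 (1.42), and 2 when adjusted over the list alone (median 0.79, camera adjusted p = 0.021; adjusted p = 0.47 with an estimated correlation). Of them 4 rose without wild-type day 4 replicate 1 and 0 with only the 6 libraries compared, and the list was not called without mutant day 4 replicate 1 (0.079) or 2 (0.052). Pluripotency genes fell in 12 of 20, and in 12 when adjusted over the list alone (median -1.35, camera adjusted p = 5.8e-08; adjusted p = 0.13 with an estimated correlation). Trophoblast genes fell in 5 of 12, and in 5 when adjusted over the list alone, with a median of -0.33 and a mean of -0.99 (camera adjusted p = 0.00034; adjusted p = 0.2 with an estimated correlation). The imprinted list had a median of 0.31 and a mean of -0.06 (camera adjusted p = 0.65, upward), and the endoderm list 0.18 and -0.01 (adjusted p = 0.91, downward).

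On day 4, 337 genes were higher and 399 lower (176 and 284 with only the 6 libraries compared). Without the 5 libraries with heart transcripts 343 were higher and 330 lower, and 231 of the 337 stayed called. The cardiac progenitor and contractile lists then had camera adjusted p of 0.0035 and 0.0041, and the BMP, streak, mesenchyme, pluripotency and trophoblast lists of 3.4e-07, 0.002, 0.0038, 9e-08 and 0.00013. The histone genes Hist1h2ao, Hist1h2ap and Hist1h2ad, near-identical copies, rose by 2.76, 2.74 and 2.34 through mutant day 4 replicate 3 alone, and without it their changes were 0.58, 0.55 and 0.61 and not called. Their calls were also lost without any 1 of the 3 wild-type day 4 libraries, with no filter and with only the 6 libraries compared. The Gata6, Tbx20, Vim and Col1a1 calls were lost with only the 6 libraries compared, and the Pdgfra call with a pseudocount of 1 (0.99).

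On day 5, 10 of 16 cardiac progenitor genes (6 without wild-type day 5 replicate 2), 5 of 11 mesenchyme genes and 5 of 13 BMP targets (8 without wild-type day 5 replicate 1) were higher in mutants, and 11 of 20 pluripotency and 5 of 12 trophoblast genes were lower. With an estimated correlation these lists had an adjusted p of 0.13, 0.17, 0.077, 0.13 and 0.13 in that order. Bmp4 was at 180 ± 6.08 scaled RPKM in mutants and 27.2 ± 13.5 in wild type (log2 change 2.87, SE 0.39, adjusted p = 8.1e-06), and the BMP antagonist Nog rose by 2.04. Hand1 rose from 200 ± 24.3 to 581 ± 89.7 (log2 change 1.54, SE 0.28, adjusted p = 0.00022), having been lower in mutants on day 3. Gata5, a cardiac and endodermal factor, rose by 1.6, and Smyd1, a methyltransferase of developing muscle, from 0.606 ± 0.2 to 3.13 ± 0.36 (log2 change 1.73, SE 0.12, adjusted p = 1.7e-09). The hindlimb factor Pitx1 rose from 1.01 ± 0.439 to 24.5 ± 6.77 (log2 change 4.05, SE 0.63, adjusted p = 4.2e-05), and the Hox genes Hoxd9 and Hoxb6 rose by 3.33 and 3.08. Tfap2c (-2.72), H19 (-4) and Cdh5, the vascular endothelial cadherin gene (-2.07), fell.

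Cardiac progenitor genes rose in 10 of 16, and in 10 when adjusted over the list alone (median 1.13, camera adjusted p = 5.7e-07; adjusted p = 0.13 with an estimated correlation). Of them 6 rose without wild-type day 5 replicate 2, and 5 with a pseudocount of 1, a filter of 5 or only the 6 libraries compared. Contractile genes rose in 7 of 23 and fell in 1, Myl4, with 9 and 1 when adjusted over the list alone (median 0.83, camera adjusted p = 3e-06; adjusted p = 0.3 with an estimated correlation). The rises were 11 with a pseudocount of 0.1 and 4 with only the 6 libraries compared. Of 11 mesenchyme genes 5 rose, among them Col1a1 (2.36), and 6 when adjusted over the list alone (median 1.22, camera adjusted p = 7.6e-05; adjusted p = 0.17 with an estimated correlation). BMP targets rose in 5 of 13, in 5 when adjusted over the list alone and in 8 without wild-type day 5 replicate 1 (median 0.99, camera adjusted p = 8.5e-08; adjusted p = 0.077 with an estimated correlation). Of 8 Wnt targets 2 rose, Dkk1 (1.03) and Notum (1.06), and 2 when adjusted over the list alone (median 0.88, camera adjusted p = 0.00056; adjusted p = 0.13 with an estimated correlation). Both genes inhibit Wnt signalling. Of the list 1 rose without wild-type day 5 replicate 2 or mutant day 5 replicate 1 or 3, without scaling, and with the same sum or a pseudocount of 1. Pluripotency genes fell in 11 of 20, and in 13 when adjusted over the list alone (median -1.14, camera adjusted p = 2.4e-08; adjusted p = 0.13 with an estimated correlation). Trophoblast genes fell in 5 of 12, and in 5 when adjusted over the list alone (median -0.86, camera adjusted p = 3.4e-05; adjusted p = 0.13 with an estimated correlation). The neural list, with 5 measured genes, had a median of -0.13 and a mean of 0.05 (camera adjusted p = 0.76, upward). The serpin genes Serpinb9e (-4.53), Serpinb9f (-4.1) and Serpinb9g (-3.85) fell, as did Dmrtc1c1 (-3.93) and Dmrtc1c2 (-3.92). Both families hold similar copies that can share reads, and are uncertain.

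On day 5, 343 genes were higher and 510 lower, and without wild-type day 5 replicate 1, 560 were higher and 613 lower. Without the 5 libraries with heart transcripts 405 were higher and 538 lower, and 283 of the 343 stayed called. The contractile and cardiac progenitor lists then had camera adjusted p of 0.00034 and 3e-06, and the mesenchyme, BMP, Wnt, pluripotency and trophoblast lists of 0.00044, 3.4e-07, 0.0022, 5.1e-07 and 0.00013. The Dkk1 call was lost without wild-type day 5 replicate 2 (0.92) or mutant day 5 replicate 3 (0.99), and with no scaling (0.97) or the same sum (0.96). The Notum call was lost without wild-type day 5 replicate 1 (0.96) or mutant day 5 replicate 1 (0.92) and with a pseudocount of 1 (0.85).

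On day 6, the last day sampled, contractile genes were higher in mutants in 19 of 23 cases, with a median log2 change of 3.01 (camera adjusted p = 2e-24; adjusted p = 0.07 with an estimated correlation). Smyd1 rose from 2.08 ± 0.392 to 12.9 ± 0.369 scaled RPKM (log2 change 2.39, SE 0.12, adjusted p = 7.5e-12). The myosin heavy chains Myh6 and Myh7 rose by 5.08 and 2.8, Myh7 from 0.152 ± 0.0923 to 4.05 ± 0.723 (SE 0.17, adjusted p = 4.4e-11). The cardiac factor Nkx2-5 rose from 5.73 ± 4.02 to 30.1 ± 3.97 (log2 change 2.5, SE 0.47, adjusted p = 0.00026), and Gata5 by a log2 change of 2.21 (SE 0.19, adjusted p = 9.1e-09). H19 fell from 1270 ± 187 to 93.5 ± 8.58 (log2 change -3.75, SE 0.35, adjusted p = 3.6e-08), and Tfap2c from 64.7 ± 21.4 to 12.3 ± 1.66 (log2 change -2.3, SE 0.29, adjusted p = 2e-06).

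All 3 mutant day 6 libraries hold the heart and globin transcripts, and the largest rises were Myl2 (7.34), Hbb-bs (7.12), Hbb-bt (6.95), Hba-a2 (5.92), Hba-a1 (5.66), Myl3 (5.16) and Cox6a2 (5.09). The globin genes have similar copies that can share reads. After subtraction of the shared signal, Myl2 was at 2.22, Myl3 at 3.25, Myh6 at 3.39, Myh7 at 2.8, Smyd1 at 2.39 and Nkx2-5 at 2.5, and these stayed called. Troponin I, Tnni3, named after its values were seen, went from 4.58 to 0.79 and was no longer called. Hba-a1 went to 0.63, Hba-a2 to 0.59 and Hbb-bs to -0.59, none of them called, while Hbb-bt stayed called at 4.26 (17 scaled RPKM in mutants against 0.51 in wild type). Of the 19 contractile genes, 16 stayed called, among them Actc1, Myl7, Myh7, Smyd1 and Ldb3, whose log2 change the subtraction did not move. When the larger excess seen in day 4 or day 5 replicate 3 was subtracted, 12 of the 19 stayed called, among them Myh6 (2.47), Myh7 (1.95), Myl3 (3.14) and Smyd1 (2.39), while Myl2 went to -0.11 and Hbb-bt to -0.29, both not called, and Tnnc1 to -4.97. That larger subtraction moved the median of all genes by -1.33 and also turned genes outside the heart signal, such as Bmp4 (-5.6), Dkk1 (-4.44), Grb10 (-3.62), Col1a1 (-1.19) and Lama1 (-1.16), while Hand2 stayed called (1.29, adjusted p = 0.032).

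Of the contractile genes 19 rose when adjusted over the list alone and 12 with a filter of 5, which keeps fewer genes, and after subtraction the list had a camera adjusted p of 3.7e-19. Cardiac progenitor genes rose in 12 of 16, and in 13 when adjusted over the list alone (median 1.29, camera adjusted p = 6.9e-08; adjusted p = 0.13 with an estimated correlation; 1.4e-07 after subtraction). Mesenchyme genes rose in 8 of 11, among them the collagen gene Col1a2 (2.28), in 9 when adjusted over the list alone and in 5 with only the 6 libraries compared (median 1.69, camera adjusted p = 1.9e-06; adjusted p = 0.13 with an estimated correlation). Endothelium and blood genes rose in 5 of 13 and fell in 2, also when adjusted over the list alone (median 1.04, camera adjusted p = 0.013; adjusted p = 0.46 with an estimated correlation; 0.024 after subtraction). The endothelial receptors Tek and Tie1 rose by 2.13 and 2.21, while Gata2 fell (-1.78). In this list 8 rose without wild-type day 6 replicate 3, 3 without mutant day 6 replicate 1, 3 with a pseudocount of 1 or only the 6 libraries compared, and 2 with a filter of 5. Of it 1 fell without wild-type day 6 replicate 2 or mutant day 6 replicate 3, and with a pseudocount of 0.1 or 1 or only the 6 libraries compared. The list was not called without wild-type day 6 replicate 1 (camera adjusted p = 0.11) or mutant day 6 replicate 2 (0.059), with a filter of 5 (0.19) or with only the 6 libraries compared (0.078). Endoderm genes rose in 4 of 9, among them the laminin gene Lama1 (1.15), and in 5 when adjusted over the list alone (median 1.03, camera adjusted p = 0.021; adjusted p = 0.2 with an estimated correlation). It was 2 of 9 without wild-type day 6 replicate 1, where Ttr (0.69) and Hhex (0.89) lost their calls and the list was not called (camera adjusted p = 0.064), 2 without mutant day 6 replicate 1, where Lama1 (0.91) and Hhex (0.95) lost theirs, and 2 with a pseudocount of 1. Hhex lost its call also without mutant day 6 replicate 2 (0.89), and Ttr with only the 6 libraries compared. The list was also not called with the same sum (0.062), no filter (0.052), a filter of 5 (0.081) or only the 6 libraries compared (0.059). BMP targets rose in 5 of 13, among them Bmp4 (2.37), and in 5 when adjusted over the list alone (median 0.81, camera adjusted p = 2.9e-06; adjusted p = 0.12 with an estimated correlation). Of 8 Wnt targets 1 rose, Dkk1 (1.26), and 1 when adjusted over the list alone (median 0.6, camera adjusted p = 0.0077; adjusted p = 0.22 with an estimated correlation).

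Pluripotency genes fell in 8 of 20, among them Zfp42 (-1.97) and Fgf4 (-1.36), and in 10 when adjusted over the list alone (median -1.02, camera adjusted p = 1.1e-06; adjusted p = 0.16 with an estimated correlation). Trophoblast genes fell in 6 of 12, among them Dlx3 (-1.67) and Krt7 (-1.35), and in 6 when adjusted over the list alone (median -1.09, camera adjusted p = 0.00043; adjusted p = 0.2 with an estimated correlation). Imprinted genes rose in 6 of 16, among them Nnat (1.85), Plagl1 (1.55) and the growth inhibitor Grb10 (1.4), and fell in 2, also when adjusted over the list alone (median 0.73, camera adjusted p = 0.021; adjusted p = 0.46 with an estimated correlation). The neural list had a median of -0.33 and a mean of -0.05 (camera adjusted p = 0.9, upward), the p53 list a median of -0.05 and a mean of 0 (0.96, upward), and the streak and cell cycle lists were not called. On day 6, 519 genes were higher and 585 lower. After subtraction 457 were higher and 672 lower, and 456 of the 519 stayed called. The mesenchyme, endoderm, BMP, Wnt, pluripotency, trophoblast and imprinted lists then had camera adjusted p of 1.4e-06, 0.016, 4.6e-06, 0.006, 2.2e-06, 0.00011 and 0.034. After the larger subtraction the cardiac progenitor, BMP, Wnt, pluripotency, trophoblast and imprinted lists were not called (camera adjusted p = 0.06, 1, 0.31, 0.42, 0.31 and 0.55). The imprinted list was also not called without wild-type day 6 replicate 2 (0.064), with a filter of 5 (0.058) or with only the 6 libraries compared (0.059), and the Tie1 and Plagl1 calls were lost with only the 6 libraries compared.

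**Figure D4:**
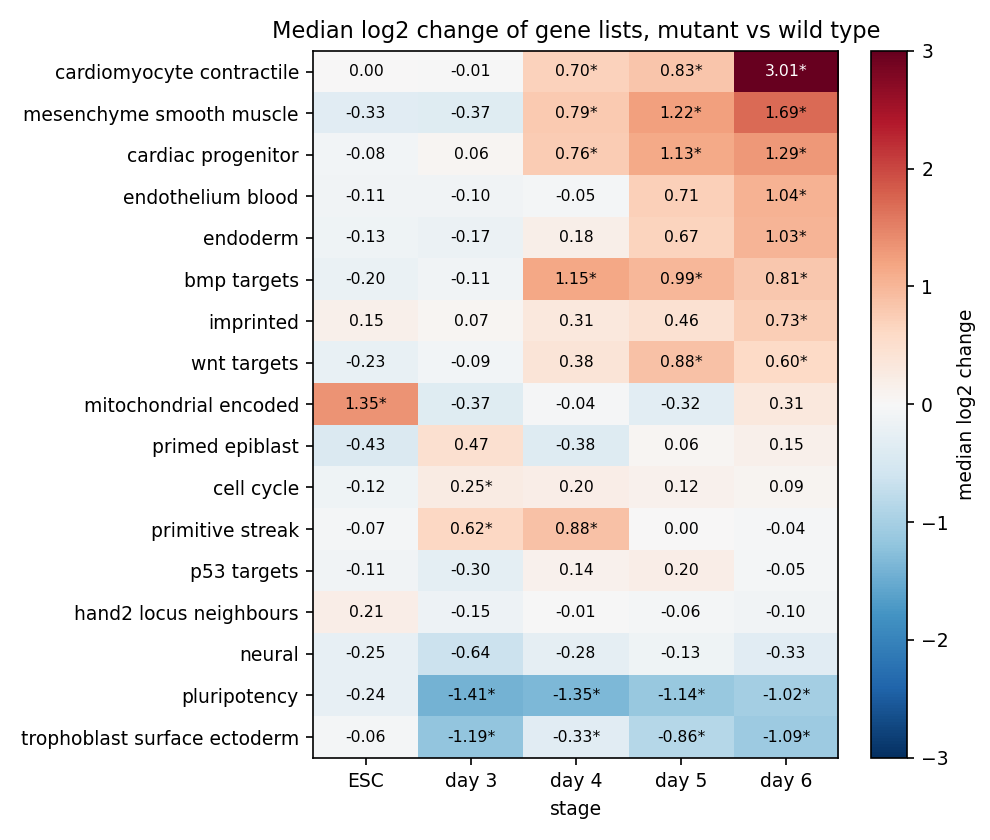
Median log2 change of each gene list, mutant against wild type, by stage, as a colour scale with the value in each cell and an asterisk where the camera adjusted p was under 0.05. Contractile genes reach 3.01 on day 6, pluripotency genes lie at -1.41 on day 3, and mitochondrially encoded genes at 1.35 in ESCs.

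The differences of successive days overlapped. Of the genes called lower, 192 were shared by days 3 and 4, 266 by days 4 and 5, and 429 by days 5 and 6, where 9.9, 14.3 and 21 would be shared by chance. Of those called higher, 60, 142 and 264 were shared, with 2.9, 8.1 and 12.5 by chance. Across genes, which are not independent replicates, the log2 changes of days 5 and 6 correlated with r = 0.86 and those of ESCs and day 6 with r = 0.02. The changes in ESCs and day 6 shared 12 higher genes (44.4 by chance) and 44 lower genes (18.3 by chance). A total of 16 genes were higher and 109 lower on all of days 3 to 6.

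**Figure D5:**
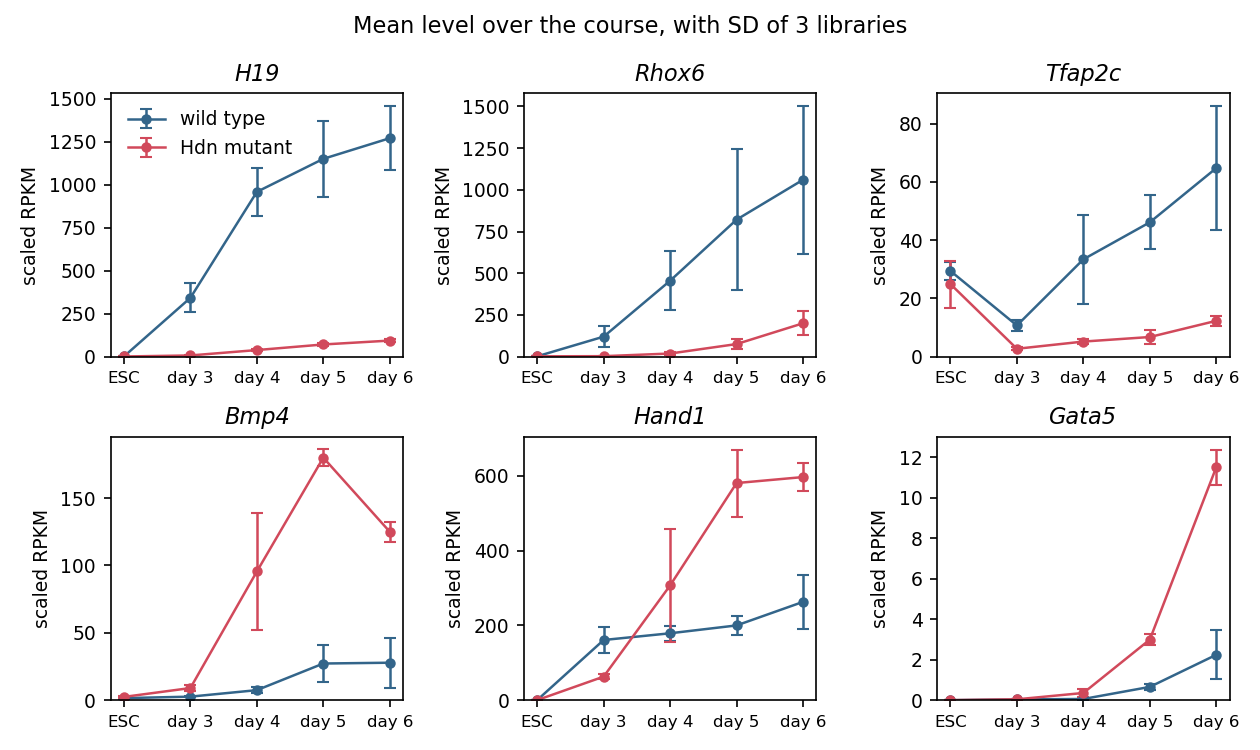
Mean scaled RPKM of single genes by stage in wild type and Hdn mutants, with the SD of 3 libraries as error bars. H19 reached 1270 in wild type and 93.5 in mutants on day 6, and Bmp4 reached 180 in mutants and 27.2 in wild type on day 5.

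Averaged over the 5 stages, H19 was lower in mutants by a log2 change of -3.67 (SE 0.16, adjusted p = 1.5e-14) and Bmp4 higher by 2.18 (SE 0.17, adjusted p = 3.8e-10). Hand2 was higher on average by 1.37 (SE 0.26, adjusted p = 1e-04) and Hpgd lower by -1.35 (SE 0.11, adjusted p = 6.3e-10). Rgcc, a cell cycle regulator, was lower by -2.45, and the X-linked Ldoc1 and Fthl17a by -3.1 and -2.98. Dlgap5, a mitotic spindle gene, was higher by 1.61 (SE 0.06, adjusted p = 5.8e-15), and Ktn1, a kinesin receptor of the endoplasmic reticulum, by 1.79. Leaving out the 5 libraries with heart transcripts removes all mutant libraries of day 6, so that average covers ESCs and days 3, 4 and 5 only. In it Myl2 went from 2.24 to 0.14, Cox6a2 from 1.58 to 0.2, Actc1 from 1.61 to 0.74 and Hand2 to 0.99, below the threshold. These drops mix the loss of the heart signal with the loss of day 6. On average 109 genes were higher and 269 lower, and 91 and 280 with all stages kept and the shared heart signal subtracted. Without the 5 libraries, and so without day 6, 79 were higher and 220 lower. The mutant difference depended on stage for 5997 genes by the limma F test.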

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

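Of the tests in this part, the ratio of Myl2 to Hbb-bs, the day 6 change of the genes called in ESCs, the heart genes low in fellow replicates, and the alternatives that subtract or leave out the heart signal were chosen after the result was seen, and the tests on heart tissue, placenta and germline marker lists and on X-linked genes were chosen after the patterns were seen, with bounds set before their own results.

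The mutant difference depended on stage for 5997 genes, a difference between time points found by the limma F test. Of 100 splits of the libraries within stages, 1, the real one, gave as many, and the highest other gave 3242, so a random assignment of libraries to genotype is argued against. Splits of libraries cannot tell the mutation from a chance difference between clones or cultures, which the labels do not describe. Without replicate 2 of each group it was 1108 genes. Compared with ESCs, 6 gene lists had another mutant difference on day 3, 7 on day 4, 7 on day 5 and 7 on day 6 by camera. The contractile list on day 6 had an adjusted p of 9.3e-13 (adjusted p = 0.34 with an estimated correlation), and none of these lists passed with an estimated correlation. A total of 68 genes were called in opposite directions at 2 stages, 48 of them between ESCs and a later day. Zfp42 was higher in mutant ESCs (1.11) and lower on day 3 (-2.13), and Hand1 was lower on day 3 (-1.33; call lost with a pseudocount of 0.1, adjusted p = 0.056) and higher on day 5 (1.54).

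The average over stages called 378 genes. Of 100 splits within stages, 1, the real one, gave as many, with 150 in the highest other, so a random assignment of libraries is argued against, with the same limit for clones and cultures. For each stage alone, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 1658 genes in ESCs (highest other 483), 476 on day 3 (0), 736 on day 4 (34), 853 on day 5 (188) and 1104 on day 6 (29), and 1 of the 10 splits gave as many at each stage. For gene lists the real values were 1, 4, 7, 7 and 10 from ESCs to day 6, the highest others 2, 6, 7, 9 and 9, and 8, 6, 3, 4 and 1 of the 10 splits gave as many. For the wild-type steps the highest others were 1, 3, 37 and 35 genes, against 5354, 333, 215 and 31 in the real splits, and 1, 1, 1 and 3 of the 10 splits gave as many. For day 6 against ESCs the real split gave 5987, the highest other 0, and 1 of the 10 as many.

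The heart and globin transcripts in 5 mutant libraries could come from RNA of heart tissue with blood, or from heart muscle and red cells formed in the cultures. The ratio of Myl2 to Hbb-bs was 0.86, 0.76, 0.74, 0.71 and 0.74 in the 5 libraries, a coefficient of variation of 0.078, but that test was made on genes whose values had been seen and decides nothing, so heart muscle and red cells formed in the cultures stay open. RNA of heart tissue as the whole cause of the contractile rise on day 6 stays open. The larger subtraction left 0.63 of the 19 genes called and took all 4 adult globin genes below wild type. The adult beta globins set its scale, so their fall does not show that the heart signal was removed. Differences between fellow replicates can also hide the heart share of genes that those replicates express. On mutant day 5, Myl7 was at 41.2 and 69.3 scaled RPKM in replicates 1 and 2 and at 16.8 in replicate 3. The first subtraction left 0.84 called but cannot decide this either, since it left Hbb-bt at 4.26 and took nothing from Actc1, Myl7, Myh7, Smyd1 and Ldb3. By its construction, a gene with a negative slope on any of the mutant days used loses nothing. The test of heart tissue RNA gave -0.39 on day 4 and 0.44 on day 5 for the excess of 16 heart genes over that of adult globin, beyond the bound against it on day 4, but that bound was wrong, since 15 of the 16 genes already stood at 10% or more of their day 6 level in the fellow replicates, and such a baseline hides a small share. The 6 genes low in those replicates, picked after their values were seen, gave 0.64 and 1.19 and decide nothing, so heart tissue RNA as a source stays open. Without the 5 libraries camera with the preset correlation still called the cardiac progenitor and contractile lists on day 4 (adjusted p = 0.0035 and 0.0041) and day 5 (3e-06 and 0.00034). These list calls of days 4 and 5 therefore do not rest on that signal. With all libraries and an estimated correlation, camera called neither list (adjusted p = 0.28 and 0.47 on day 4, 0.13 and 0.3 on day 5). Whether the differences of days 4 and 5 come from the Hdn mutation or from another difference between the lines stays open.

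Of 19 measured placenta genes, 10 to 13 were lower in mutants on days 3 to 6, and the genes called lower were enriched for the X chromosome. A share of trophoblast-like cells that is smaller in mutant cultures stays open. The higher of the placenta genes' median log2 changes on days 5 and 6 was -1.3. Without the 3 X-linked genes among them the medians were -1.3 on day 5 and -1.39 on day 6. But the placenta genes measure the pattern again, and lower levels per cell would give the same. Cdx2 (2.26 on days 4 and 5) and Hand1 (1.54 on day 5), which trophoblast also expresses, were higher. An X chromosome less active throughout is argued against, since X-linked genes differed from autosomal ones by a median of -0.03 on day 5 and 0.06 on day 6. Silencing by DNA methylation that was lost in the wild-type line stays open: germline genes known to be silenced that way had medians of -0.78 on day 3 and -0.29 on day 6, between the bounds set beforehand, with 8 of 18 measured.

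The 1658 genes that differ between mutant and wild-type ESCs were found although Hdn had 0 reads in all ESC libraries. A gene length bias between libraries stays open, since the ESC log2 change correlated with the gene span across genes (Spearman rho 0.21, with a span for 94.6% of genes), between the bounds set beforehand. As a set, the 1658 genes did not keep their difference to day 6. They changed on that day by a median of 0.01 of their ESC change or less, also among the 1305 of them at 1 scaled RPKM or more. That test was chosen after the result was seen and does not decide on a difference between the lines, such as one between clones. A median does not cover a subset, and ESCs and day 6 shared 44 lower genes (18.3 by chance). Wild-type ESCs may also differ from the later wild-type cultures, as the Eif2s3y levels below show. A difference that lasts in part stays open: across genes the ESC changes correlated with those of days 3, 4, 5 and 6 with r = 0.34, 0.3, 0.02 and 0.02, the Y-linked Kdm5d had 45 to 174 reads in mutant libraries against 3 to 32 in wild type over all stages, and Eif2s3y was at 0.368 scaled RPKM in wild-type ESCs and at 3.71 to 4.39 on later wild-type days. The split between rises and falls moved with the scaling and with mutant ESC replicate 1, without which 2552 genes were called, and an effect of the mutation in ESCs was not tested.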

How the results depend on the processing

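The alternatives without the 5 libraries with heart transcripts and with their signal or a larger signal subtracted were chosen after the data were seen. Among named genes, leaving out a replicate kept the call and direction in 2183 tests, gained a call in 9 and lost it in the rest, and the other alternatives kept it in 4613, gained 24, lost 152 and reversed 24. Of the reversals, 1 was Hbb-bs on day 6 after subtraction (-0.59), and the rest came on day 6 from the larger subtraction, which moved the median of all genes by -1.33 and gave 8176 genes (193 higher, 7983 lower) and 6 lists: Myl2 (-0.11), Hbb-bs (-0.79), Hbb-bt (-0.29), Hba-a2 (-2.16), Hba-a1 (-2.18), Cox6a2 (-0.45), Wnt3 (-2.08), Pdgfra (-1.36), Pdgfrb (-2.06), Col1a1 (-1.19), Vim (-2.72), Pecam1 (-1.5), Lama1 (-1.16), Dab2 (-1.67), Stmn2 (-2.97), Bmp4 (-5.6), Dkk1 (-4.44), Tcf7 (-2.81), Fas (-0.9), Grb10 (-3.62), Eif2s3y (-3.17), mt-Co2 (-12.14) and mt-Co1 (-8.9). By its construction it scales up ordinary differences between replicates. No scaling, the same sum and quantile normalization kept each total of called genes and lists within 1.5 times, but not each direction: genes lower in mutant ESCs were 257 without scaling and 268 with the same sum (444 in the reported fit), falls in the wild-type day 4 step 39 with the same sum (66), and falls in the last step 11 with quantile normalization (7). Without the trend, limma's SE moved by a median of 0.4% and 3 to 35 genes per comparison crossed an adjusted p of 0.05, none with a log2 change of at least 1, and 40 crossed it in the F test with the total kept, so that setting changed too little to test stability. A pseudocount of 0.1 gave 856 genes on day 3, 1264 on day 4, 1303 on day 5, 749 on average, and 538 and 343 in the wild-type steps to days 4 and 5. A pseudocount of 1 gave 232 on average and 136 in the step to day 5. No filter gave 2 lists in ESCs and 7 on day 3, and a filter of 5, which tests fewer genes, gave 1001 genes in ESCs, 565 on day 5, 669 on day 6, 11 in the last wild-type step, 3945 from ESCs to day 6, and 3566 dependent on stage. Adjusted p alone, with no fold threshold, gave 6461, 2309, 3127, 2958 and 3744 genes from ESCs to day 6, 7521 on average, 10229, 1087, 573 and 111 in the wild-type steps, and 10468 from ESCs to day 6. Only the 6 libraries compared, with fewer samples to estimate the spread, gave 460 genes on day 4, 2.17 for Hand2 on day 6 (adjusted p = 0.087, and 0.00015 to 0.064 in the other alternatives), and 0 and 0 in limma for the wild-type steps to days 5 and 6 (1721 and 662 genes at an unadjusted p under 0.05). Replicate number as a block gave 53 in the last step, and the labels do not say whether a replicate number marks a shared day or culture. Camera with an estimated correlation called 0 lists in ESCs and 0, 0, 0 and 0 on days 3 to 6 (0, 3, 3, 6 and 7 at an unadjusted p under 0.05), and fry called 4, 5, 8, 11 and 11. Leaving out 1 replicate gave 1285 to 2552 genes in ESCs, 437 to 511 on day 3, 631 to 944 on day 4, 698 to 1173 on day 5, 840 to 1322 on day 6, 321 to 433 on average and 1108 to 5479 dependent on stage. In wild type it gave 5015 to 5652, 209 to 475, 114 to 364 and 15 to 102 for the steps, and 5836 to 6240 from ESCs to day 6. Lists ranged over 1 to 1, 3 to 5, 5 to 8, 7 to 7 and 8 to 10, and Hand2 on day 6 from 1.43 to 3.01. Beyond fewer genes or samples, the cause of these changes was not tested. Depth limits Hdn, whose reads in ESCs and on day 3 are within the 3 that a count of 0 allows in all but 1 library.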

Other observations

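The Fisher tests on X-linked genes and the marker lists in this part were chosen after the patterns were seen.

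Genes lower in mutants were enriched for the X chromosome. On days 3, 4, 5 and 6, 9.7, 12.2, 13 and 11.2% of the lower genes were X-linked, against 3.8% of the genes tested (odds ratios 2.86, 3.8, 4.2 and 3.51; Fisher's exact test, adjusted p = 1.7e-06, 3.2e-12, 2e-17 and 3.2e-14 over 10 tests). They include the Rhox homeobox cluster, the Xlr genes and the placenta genes Plac1 and Nrk, lower on both days 5 and 6. In ESCs, 6.2% of the higher genes were X-linked (odds ratio 1.78, adjusted p = 9.4e-05). These genes lie in clusters and are not independent.

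Of 19 measured placenta genes, 10, 11, 13 and 11 were lower on days 3, 4, 5 and 6 and 1, 1, 0 and 0 higher, with medians of -1.14, -1.38, -1.3 and -1.31. In ESCs 1 was lower. Of 8 measured germline genes silenced by DNA methylation, 3, 3, 2 and 2 were lower on days 3 to 6, while 3 were higher and 1 lower in ESCs. Heart tissue genes, 16 of 22 measured, were higher in 2, 3 and 8 cases on days 4, 5 and 6, with medians of 0.31, 0.62 and 1.05, and 4 were lower on day 3. The 4 early cardiac genes Hand2, Tbx20, Myl7 and Gata5 were higher in 2, 3 and 4 cases on days 4, 5 and 6. The 2 adult beta globins were higher on day 6 (median 7.04). The 3 embryonic globins were not called on any day, with a median of 1.79 on day 6.

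The share of RPKM removed by the subtraction was 0.24, 0.48, 1.13, 2.92 and 2.49% in the 5 libraries with heart transcripts. The embryonic globin Hbb-bh1 was at 0 in mutant day 4 replicate 3 and at 109 scaled RPKM in wild-type day 6 replicate 3.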
